A study of Mus musculus with 6 samples.

How the data were processed

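RNA was measured by high-throughput sequencing in skin of 6 mice, 3 treated with CST and 3 treated with Yoda1, as the labels give it. Per the labels, total RNA was extracted with a Qiagen RNeasy kit and the drugs were applied to the skin as gels. The labels also tag each sample as keratinocytes and as skin cells, and the tissue is given as skin; the libraries were treated here as whole skin. Groups and mouse numbers were taken from the sample titles. The mice of a group were labelled as separate animals.

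The authors deposited 1 table of 57010 genes with FPKM values (fragments per kilobase of gene, scaled to the mapped depth) for the 6 libraries, gene symbols and gene annotation, and no counts. The aligner, the counting tool and the library's strandedness are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10. Of the 52081 gene identifiers that matched the GENCODE M21 annotation of GRCm38, 2.9% had a deposited start equal to the GRCm38 start, so the deposited positions were not used, and the positions given are those of GENCODE M21 on GRCm38, matched on the Ensembl gene identifier. In 26313 genes every library was listed at 0. All columns of values matched a sample. Some symbols were shared by more than 1 row (297 rows), so genes were handled by identifier.

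Depth was recovered from the steps of the FPKM values. The smallest values of a gene in 2 libraries stood in the ratio of their depths, and 2960 short genes counted over their whole span set the absolute scale. The depths came out between 23791352 and 29620526 reads per library. With these depths every gene above 0 (30697 genes) gave whole reads in each library within 0.0001 reads, whereas with deliberately wrong depths 0% of 2000 genes did. The recovered reads summed to between 99.66% and 99.71% of the depth. At this depth 1 read on a gene of 1 kb is worth 0.0338 to 0.042 FPKM, and the median tested gene held 631 reads per library. These figures cover counting error only.

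The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), two-sided, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. It was run on the 14588 genes with a mean of at least 1 FPKM over the 6 libraries. Changes are CST minus Yoda1 on the log2(FPKM + 1) scale, which understates the change of genes with low values. No scaling was added to the deposited FPKM.

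Gene lists of pathways, skin cell types and other cell types that skin can hold were written before the data were examined, 44 in all with 965 members, of which 962 had a row. The 42 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move one way on balance and does not compare the list with other genes. A list's score in a library is the mean log2(FPKM + 1) of its tested members. Exact permutation of 3 libraries against 3 cannot give a two-sided p below 0.1, so list scores are described without one. GO, KEGG and Reactome terms in the deposited annotation with 15 to 300 tested members (3444 terms) were tested in the same way.

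The genes named follow a rule written before the data were examined. It takes a fixed panel of 10 genes, the 10 genes of each direction with the smallest unadjusted p where none passed the threshold (predicted and clone names left out), and up to 4 members with the smallest p of each list described. Genes of close families, such as Ifit, Gbp, the globins, Krtap, Stfa and Ccl3 with Ccl4, can share reads, and how the authors' counting split such reads is not given in the sources used here, so the values of single members are uncertain to that extent.

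Both tests were tested on simulated data drawn from the means and depths of these libraries. With a dispersion of 0.052, which matches the median spread within groups, 48% of 50 genes changed by 2-fold, 92% of those changed by 4-fold, 100% by 8-fold and 96% by 16-fold were recovered over 14588 genes, with 18 false calls. Set beside the 24, 46, 50 and 48 genes recovered, the 18 false calls were a larger share of the calls than the 0.05 aimed at. In these simulated data all genes had the same dispersion, so the recovered shares need not hold for genes of wider spread. The list test called 20 of 20 lists shifted by a factor of 2 and 0 of 100 unshifted lists, with genes drawn independently of each other at a dispersion of 0.2. In the real lists the estimated correlation ran from -0.02 for the Piezo list to 0.91 for skeletal muscle, and was 0.46 for the interferon list. The simulation therefore does not show how the preset correlation behaves for correlated lists.

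Alternatives planned before the data were examined covered the pseudocount, the filter on low values, the scaling between libraries, genes with a large share of the total, the variance model, library weights, mouse number as a block, each library left out in turn and an estimated inter-gene correlation. Chosen after seeing the data were limma-voom on the recovered reads, leaving out CST mouse 1 and Yoda1 mouse 3 together, and the muscle, macrophage or neutrophil score as a covariate. Count models planned for recovered reads were not run, because the deposited unit is FPKM, and limma-voom stands in their place. Figures were drawn with matplotlib 3.10.9 from the same values.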

Results

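Skin RNA was sequenced from 6 mice when a diabetic ulcer experiment ended, with 1 library per mouse. In 3 mice the gel carried CST, for which the series title has cortistatin, a neuropeptide related to somatostatin. In the other 3 it carried Yoda1, a small synthetic molecule that opens the mechanosensitive calcium channel Piezo1. Untreated or vehicle-treated skin was not analysed here, so each value below sets one treatment against the other. The depth behind the FPKM values was 24115479, 27707128 and 29042514 reads in CST mice 1 to 3 and 29620526, 29308343 and 23791352 in Yoda1 mice 1 to 3. Between 13898 and 14665 genes reached 1 FPKM per library, and the Pearson correlation of log2(FPKM + 1) across genes was 0.915 to 0.974 over the 15 pairs of libraries. Mitochondrially encoded transcripts took 6.72% of the FPKM sum in CST mouse 1 and 7.61% in Yoda1 mouse 3, against 3.25% to 3.81% in the other 4 libraries. Those 2 libraries also lay at one end of the first principal component, which held 38.0% of the variance. Gene values below are mean FPKM ± SD over the 3 mice of a group.

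The comparison set skin treated with CST against skin treated with Yoda1, and whether Piezo1 was active in that skin was not measured. Transcripts of the type I interferon response, which mark antiviral signalling downstream of nucleic acid sensors, were lower in CST skin in all 28 of the genes measured, with a median log2 change of -0.83 (1.78-fold). Skeletal muscle transcripts were higher in CST skin in all 26 of the genes measured, with a median log2 change of 3.41. Neutrophil transcripts (median 1.00) and cytokine and chemokine transcripts (median 0.51) were also higher in CST skin, and fibrillar collagen transcripts (median -0.70) were lower. These list calls were all lost with an estimated correlation (smallest adjusted p = 0.525 with an estimated correlation), and the cytokine (0.22) and collagen (-0.08) lists were not called with the neutrophil score as a covariate. No single gene passed the threshold: limma called 0 of 14588 genes, with a smallest adjusted p of 0.521. At an unadjusted p under 0.05 there were 584 genes, 469 higher and 115 lower in CST, and limma-voom on recovered reads gave 0 calls and 599 such genes. Without any difference that threshold passes on average a share of 0.05 of the 14588 genes, and both counts lay below that.

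In 962 genes (6.59%) the 3 values of one group all lay above the 3 of the other, where chance gives 10%; 659 of these were higher in CST. The median log2 change over all genes was -0.01. A single library moved the count of called genes. Without Yoda1 mouse 2 limma called 136 genes, 135 of them higher in CST and 25 of them in the skeletal muscle list. Without CST mouse 2 it called 8 genes, all higher in CST. Without Yoda1 mouse 3 it called 0, with 1671 genes at an unadjusted p under 0.05. With library weights estimated by limma, which ran from 0.193 to 12.8, it called 1348 genes, 655 of them higher in CST.

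**Figure D1:**
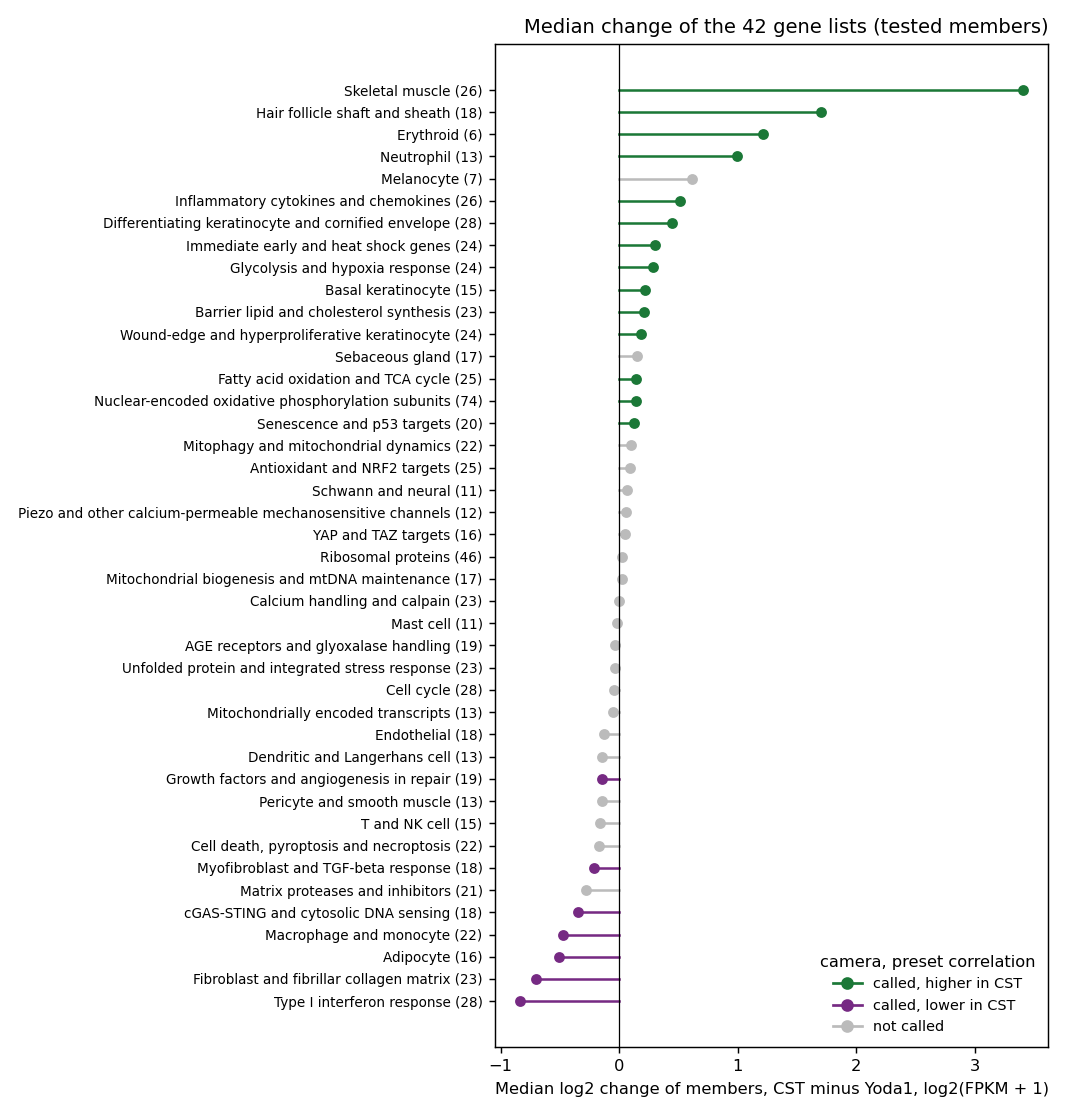
Median log2 change (CST minus Yoda1, log2(FPKM + 1) scale, horizontal axis) of the tested members of 42 gene lists, with the number of members in brackets; each line runs from 0 to the median. Green and purple mark the 14 lists called higher and the 7 called lower in CST by camera with a preset correlation, from 3.41 for skeletal muscle to -0.83 for the type I interferon response; grey marks lists that were not called, and with an estimated correlation 0 lists were called.

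With the preset correlation camera called 21 of the 42 lists, 14 higher and 7 lower in CST. With an estimated correlation it called 0 lists (smallest adjusted p = 0.525), and fry's adjusted p called 0. The calls below are those with the preset correlation, and the adjusted p with an estimated correlation stands beside each.

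The 10 genes lower in CST with the smallest unadjusted p, none of which passed the adjusted threshold, were led by Clec12a, an inhibitory C-type lectin of myeloid cells (ENSMUSG00000053063, chromosome 6, 129342691 to 129365303 on GRCm38). Clec12a measured 8.89 ± 1.18 in CST and 28.4 ± 3.16 in Yoda1 skin, a log2 change of -1.58 (SE 0.21, adjusted p = 0.521 by limma). Of the other 9, Ifit1, Ifit2, Ifit3, Mx2, Ifi44, Gbp2, Gbp3 and Phf11d are known as interferon-induced genes. Gbp3 had a log2 change of -1.22. Phf11d measured 7.11 ± 0.925 and 18.5 ± 4.69, Ifi44 3.38 ± 0.585 and 11.9 ± 4.85, and Gbp2 26.4 ± 1.47 and 47.5 ± 5.70 in CST and Yoda1 skin. Rpl39l, a paralogue of a ribosomal protein gene, measured 8.59 ± 1.83 and 21.2 ± 5.90. All 10 were lower in each CST mouse than in each Yoda1 mouse.

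The 10 genes higher in CST with the smallest unadjusted p, which did not pass either, included several genes of striated muscle. Smtnl1, a smoothelin-like protein of muscle (ENSMUSG00000027077, chromosome 2, 84811176 to 84822652 on GRCm38), measured 11.2 ± 3.60 in CST and 0.641 ± 0.841 in Yoda1 skin, a log2 change of 2.96 (SE 0.39, adjusted p = 0.521 by limma). Mylk2, the myosin light chain kinase of skeletal muscle, measured 15.6 ± 9.47 and 0.873 ± 1.09. Sbk2 measured 19.5 ± 10.8 and 1.68 ± 2.37, Asb12 3.69 ± 0.955 and 0.419 ± 0.623, Pde4dip 22.7 ± 8.50 and 5.33 ± 2.32, and Ndrg2 318 ± 109 and 80.9 ± 28.8, and the sodium pump subunit gene Atp1b1 had a log2 change of 1.63. Of the hair shaft genes, Krtap3-1 measured 5.50 ± 3.66 and 0.0565 ± 0.0978, and Krtap22-2 measured 7.74 ± 6.77 in CST skin and was listed at 0 in each Yoda1 library. Chac1, a glutathione-degrading enzyme induced by the integrated stress response, measured 6.60 ± 1.83 and 2.17 ± 0.198.

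**Figure D2:**
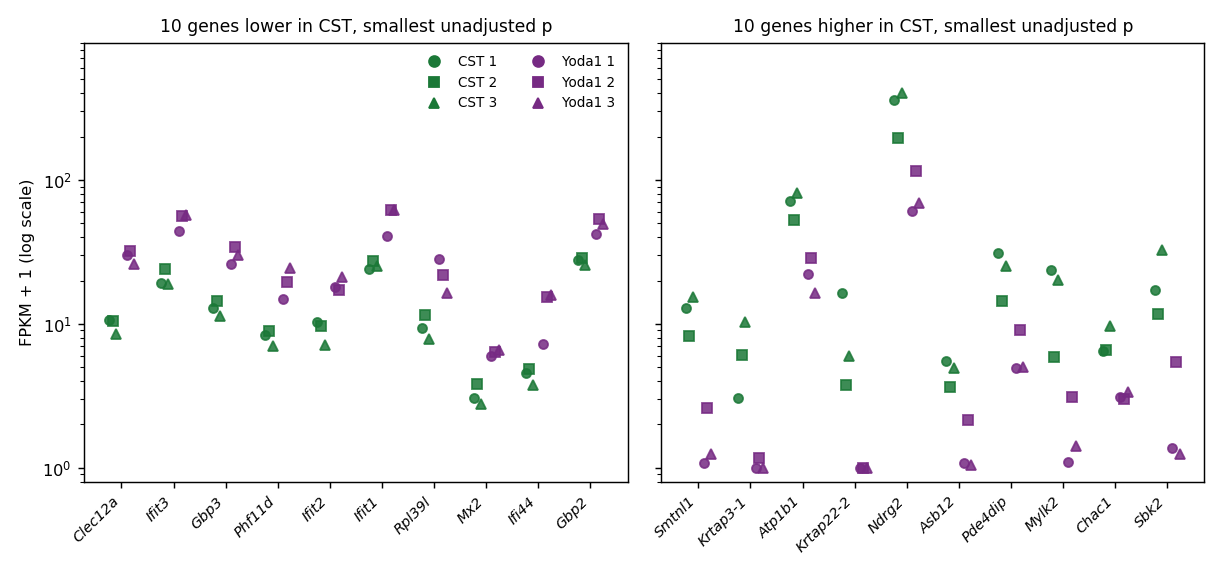
FPKM + 1 (log axis) of the 10 genes lower in CST (left) and the 10 higher in CST (right) with the smallest unadjusted p, for each of the 3 CST and 3 Yoda1 libraries; a point is 1 mouse. In each of these genes the 3 values of one group lay above the 3 of the other, as for Clec12a with at most 9.62 FPKM in CST and up to 31.3 in Yoda1, and none passed the adjusted threshold.

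The type I interferon list was lower in CST (camera adjusted p = 3.37e-35; adjusted p = 0.525 with an estimated correlation; fry unadjusted p = 0.0137). Of its 28 members 0 passed adjusted over all genes and 18 passed adjusted over the list alone, and in 20 members all Yoda1 values lay above all CST values and in 0 the reverse, where chance gives 10% for both directions together. Ifit3, an interferon-induced protein with tetratricopeptide repeats (chromosome 19, 34583531 to 34588731 on GRCm38), measured 19.7 ± 2.84 in CST and 51.5 ± 7.46 in Yoda1 skin (log2 change -1.34). Ifit1 measured 24.5 ± 1.72 and 54.0 ± 12.4 (log2 change -1.08), Ifit2 8.03 ± 1.67 and 17.9 ± 2.07 (-1.08), and Mx2 2.22 ± 0.562 and 5.30 ± 0.321 (-0.98). Mx2 belongs to a family of dynamin-like antiviral GTPases, but GENCODE M21 lists it as a polymorphic pseudogene. The list score was 4.21, 4.41 and 3.82 in the CST libraries and 4.77, 5.22 and 5.03 in the Yoda1 libraries. Its median stayed between -1.19 and -0.55 over the 23 alternatives other than the estimated correlation, with the list called in all 23.

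The list of cGAS-STING and cytosolic DNA sensing genes was also lower in CST, with 15 of 18 members negative and a median log2 change of -0.35 (camera adjusted p = 6.82e-06; adjusted p = 0.525 with an estimated correlation). Adjusted over the list alone 0 members passed. The members with the smallest p are themselves known as interferon-induced: Irf7, a transcription factor of interferon genes, measured 75.2 ± 26.9 and 179 ± 67.2 (log2 change -1.23), Zbp1 22.8 ± 3.61 and 47.5 ± 19.1 (-0.97), Ifi203 26.8 ± 9.80 and 47.2 ± 7.07 (-0.85) and the RNA sensor gene Rigi had a log2 change of -0.67. Without Yoda1 mouse 1 the list's median was -0.21, and the list was still called (adjusted p = 1.84e-06).

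Of the fixed panel, no gene passed the threshold. Piezo1 (chromosome 8, 122481698 to 122551329 on GRCm38), the channel that Yoda1 opens, measured 23.5 ± 1.52 in CST and 25.3 ± 6.58 in Yoda1 skin, a log2 change of -0.07 (SE 0.24, limma adjusted p = 1.000). Sting1, the adaptor that cGAS activates (chromosome 18, 35733679 to 35740554), measured 27.8 ± 9.75 and 39.1 ± 19.7, a log2 change of -0.37 (SE 0.45), with values of 46.0, 54.4 and 16.8 in the Yoda1 mice. Cgas had a log2 change of -0.33 (SE 0.31) and the kinase gene Tbk1 one of 0.00 (SE 0.28), and Irf3 measured 56.0 ± 13.6 and 51.2 ± 3.63. Ager, the receptor for advanced glycation end products, measured 2.75 ± 0.596 and 1.56 ± 0.544, a log2 change of 0.56 (SE 0.25) with each CST value above each Yoda1 value. Glo1, the glyoxalase that removes methylglyoxal, had a log2 change of 0.11 (SE 0.25). Ppargc1a, a coactivator of mitochondrial biogenesis, measured 1.16 ± 0.309 and 0.393 ± 0.188, with each CST value above each Yoda1 value. It lay below the filter and so had no test, as did Cort (0.172 ± 0.178 and 0.0835 ± 0.0763) and the receptor gene Sstr2 (0.288 ± 0.361 and 0.0987 ± 0.0273).

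**Figure D3:**
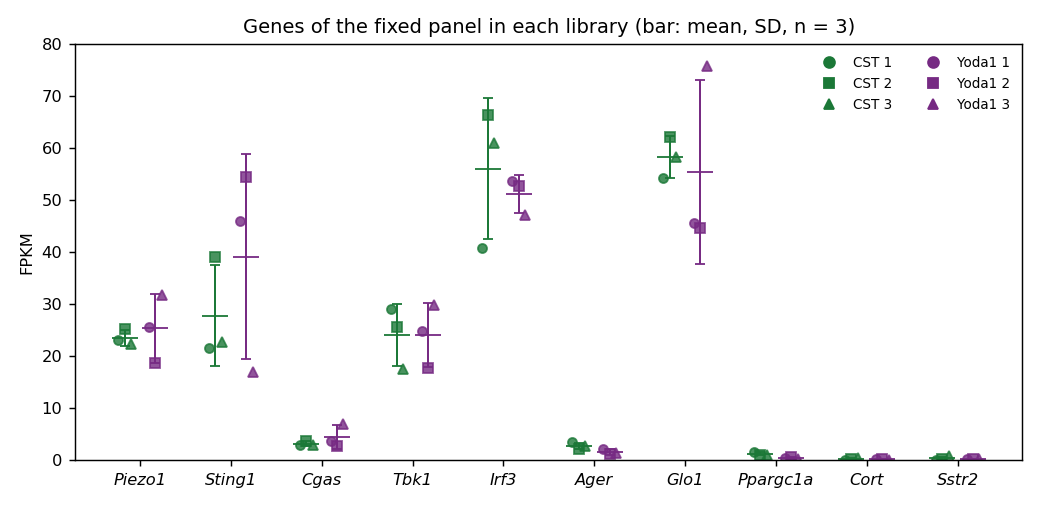
FPKM of the 10 panel genes in each of the 3 CST and 3 Yoda1 libraries (points), with the mean and SD of each group (bar, n = 3). The groups overlapped for Piezo1, Sting1, Cgas, Tbk1, Irf3 and Glo1, and Ager lay at 2.17 to 3.36 FPKM in CST and 1.11 to 2.16 in Yoda1. Ppargc1a, below the filter, lay at 0.974 to 1.51 in CST and 0.207 to 0.584 in Yoda1.

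The lists written for Piezo1 and its neighbours were not called. Piezo and other calcium-permeable mechanosensitive channels had a median log2 change of 0.06 over 12 members (camera adjusted p = 0.856), calcium handling and calpain 0.00 over 23 (0.991), YAP and TAZ targets 0.05 over 16 (0.847), and AGE receptors and glyoxalase handling -0.03 over 19 (0.999). Of the cortistatin and receptor list 1 of 9 genes was tested, so it was not tested as a list.

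Skeletal muscle genes made the widest gap between the groups (camera adjusted p = 4.31e-39; adjusted p = 0.525 with an estimated correlation). Of the 26 members 0 passed adjusted over all genes and 25 adjusted over the list alone, and in 23 members each CST value lay above each Yoda1 value. Myh4, the fast IIb myosin heavy chain, measured 266 ± 172 in CST and 15.8 ± 22.1 in Yoda1 skin, and the muscle creatine kinase gene Ckm 734 ± 347 and 66.2 ± 93.8. The calcium release channel gene Ryr1 measured 16.5 ± 3.79 and 3.19 ± 3.98, and Tcap, a Z disc protein gene, 169 ± 86.1 and 16.2 ± 23.4. The list took 2.90%, 1.52% and 2.61% of the FPKM sum in the CST libraries and 0.0763%, 1.11% and 0.174% in the Yoda1 libraries. Its score of 6.98 in Yoda1 mouse 2 lay close to the 7.36 of CST mouse 2, and the median log2 change was 4.80 without Yoda1 mouse 2 and 2.33 without Yoda1 mouse 1.

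**Figure D4:**
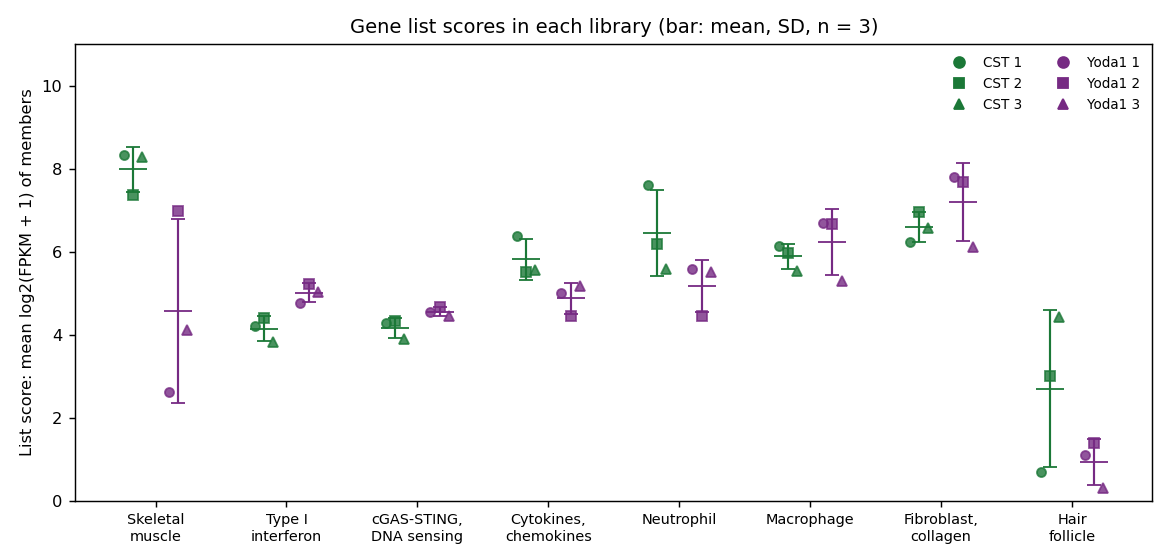
Score of 8 gene lists (mean log2(FPKM + 1) of the tested members, vertical axis) in each of the 3 CST and 3 Yoda1 libraries (points), with the mean and SD of each group (bar, n = 3). The interferon scores of the CST libraries (3.82 to 4.41) lay below those of the Yoda1 libraries (4.77 to 5.22), and the muscle scores (7.36 to 8.32) lay above them (2.62 to 6.98).

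Glycolysis and hypoxia response genes had a median log2 change of 0.28, with 20 of 24 members positive (camera adjusted p = 1.80e-05; adjusted p = 0.585 with an estimated correlation). Aldoa, the aldolase abundant in muscle, measured 2130 ± 523 in CST and 997 ± 287 in Yoda1 skin, and the hexokinase gene Hk2 38.5 ± 8.40 and 24.2 ± 6.36. The glycolysis list was not called without CST mouse 1 (median 0.14, adjusted p = 0.160) or with the muscle (0.19, adjusted p = 0.309) or neutrophil score (0.04, 0.957) as a covariate, and its median was 0.48 without CST mouse 3 and 0.44 without Yoda1 mouse 3. Nuclear-encoded oxidative phosphorylation subunits had a median of 0.14, with 63 of 74 positive (camera adjusted p = 0.0101; adjusted p = 0.756 with an estimated correlation). That call was lost without CST mouse 3 (median 0.05, adjusted p = 0.520), Yoda1 mouse 1 (0.14, 0.276) or Yoda1 mouse 3 (-0.02, 0.636), and with the muscle score as a covariate the list was called lower in CST (-0.16, 5.63e-05). Its median was 0.25 without CST mouse 1 and 0.29 without Yoda1 mouse 2. Each CST library had a higher muscle score than each Yoda1 library, so the muscle covariate partly stands for treatment. Fatty acid oxidation and TCA cycle genes had a median of 0.14, with 21 of 25 positive (camera adjusted p = 0.0126; adjusted p = 0.753 with an estimated correlation), and were not called without CST mouse 2 (0.11, adjusted p = 0.0570), CST mouse 3 (0.08, 0.215) or Yoda1 mouse 3 (-0.01, 0.643), with a median of 0.24 without CST mouse 1, and they were not called with the muscle score as a covariate either (0.10, 0.276). Mitochondrially encoded transcripts had a median of -0.05 (camera adjusted p = 0.825) and were called lower in CST without CST mouse 1 (-0.36, adjusted p = 0.00155) and with the neutrophil score as a covariate (-0.66, 0.000224). Their median was 0.21 without Yoda1 mouse 3, 0.11 without CST mouse 2 and 0.08 without CST mouse 3, where they were not called. Mitochondrial biogenesis and mtDNA maintenance (0.02, camera adjusted p = 0.699) and mitophagy and mitochondrial dynamics (0.10, 0.0662) were not called. The mitophagy list was called higher in 4 of 24 alternatives: without CST mouse 3 (0.13, 0.0423), with quantile normalization (0.07, 0.0280), with mitochondrially encoded and muscle genes removed (0.10, 0.0497) and with the macrophage score as a covariate (0.08, 0.0257).

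Neutrophil genes were higher in CST, with 12 of 13 members positive (camera adjusted p = 2.44e-09; adjusted p = 0.525 with an estimated correlation) and 1 member past the threshold adjusted over the list alone. That member was Hdc, histidine decarboxylase, with 132 ± 86.7 in CST and 22.3 ± 11.1 in Yoda1 skin; it also stands in the mast cell list. Trem1 measured 20.7 ± 16.6 and 4.07 ± 2.78, the decoy receptor gene Il1r2 88.6 ± 26.1 and 44.8 ± 15.9, and Stfa2l1 640 ± 797 and 71.9 ± 59.3. The neutrophil score was 7.60, 6.19 and 5.58 in CST and 5.57, 4.45 and 5.51 in Yoda1 libraries. Without CST mouse 1 the median was 0.57 (adjusted p = 0.00397), and without CST mouse 3 it was 1.57. The list took 1.74%, 0.304% and 0.284% of the FPKM sum in CST mice 1 to 3 and 0.258%, 0.112% and 0.589% in Yoda1 mice 1 to 3, so by share CST mouse 1 stood apart and Yoda1 mouse 3 lay above CST mice 2 and 3.

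Inflammatory cytokine and chemokine genes were higher in CST, with 18 of 26 positive (camera adjusted p = 3.15e-06; adjusted p = 0.525 with an estimated correlation; fry unadjusted p = 0.0741) and 8 past the threshold adjusted over the list alone. The macrophage inflammatory proteins Ccl4 and Ccl3 measured 808 ± 778 and 678 ± 599 in CST and 55.3 ± 32.8 and 52.6 ± 34.6 in Yoda1 skin, with log2 changes of 3.66 and 3.61. Il1b measured 538 ± 440 and 83.3 ± 37.0, and Tnf 40.4 ± 38.5 and 3.76 ± 2.13. In CST mouse 1, Ccl4 stood at 1703 FPKM against 296 and 425 in CST mice 2 and 3. With the neutrophil score as a covariate the cytokine list was not called (median 0.22, adjusted p = 0.341).

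Immediate early and heat shock genes were higher in CST in 20 of 24 members (median 0.30, camera adjusted p = 1.95e-05; adjusted p = 0.525 with an estimated correlation), with Ier3 at 328 ± 209 and 95.6 ± 33.7 and Jun at 59.5 ± 14.2 and 34.7 ± 5.97. Their median was 0.47 without Yoda1 mouse 3, 0.19 without Yoda1 mouse 1 and 0.18 without CST mouse 3, with the list called each time. With the macrophage (0.11, adjusted p = 0.0537) or neutrophil score (0.29, adjusted p = 0.267) as a covariate the list was not called. Senescence and p53 targets had a median of 0.13 (15 of 20 positive, camera adjusted p = 0.0380; adjusted p = 0.525 with an estimated correlation), a call lost without CST mouse 1 (median 0.22, adjusted p = 0.120), CST mouse 2 (0.09, 0.113), Yoda1 mouse 2 (0.11, 0.129) or Yoda1 mouse 3 (0.19, 0.267). In the unfolded protein and integrated stress response list the median was -0.04 and the mean 0.14, and the list was not called (camera adjusted p = 0.520), but 2 of 23 members passed adjusted over the list alone. These were Chac1 and Ppp1r15a, a phosphatase subunit that reverses eIF2-alpha phosphorylation, the latter at 107 ± 59.8 in CST and 23.7 ± 1.13 in Yoda1 skin. Ddit3, a stress transcription factor, measured 23.0 ± 4.75 and 13.6 ± 1.83. In the cell death list (median -0.17, mean -0.02, camera adjusted p = 0.208) the inflammasome gene Nlrp3 measured 30.1 ± 24.1 and 4.17 ± 2.11 and passed adjusted over the list alone, and the necroptosis gene Mlkl measured 13.4 ± 3.81 and 20.5 ± 1.84. Without CST mouse 1 the cell death list was called lower (-0.16, adjusted p = 0.0459), with uncalled medians of -0.28 without CST mouse 2 and -0.09 without CST mouse 3, and without Yoda1 mouse 3 the unfolded protein list was called higher (0.06, adjusted p = 0.0197). Antioxidant and NRF2 targets were not called (median 0.09, camera adjusted p = 0.0738), with Hmox1 at 373 ± 94.2 and 211 ± 69.2 and Slc7a11 at 11.5 ± 9.54 and 3.57 ± 2.78, and they were called higher in 4 of 24 alternatives, among them without CST mouse 3 (0.15, adjusted p = 0.0126).

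Macrophage and monocyte genes were lower in CST in 19 of 22 members (median -0.47, camera adjusted p = 0.00108; adjusted p = 0.727 with an estimated correlation). Lyz2 measured 625 ± 203 in CST and 1315 ± 617 in Yoda1 skin, and Adgre1, which encodes F4/80, 37.6 ± 13.5 and 68.8 ± 27.5. The lipid receptor gene Trem2 had a log2 change of -1.07. Spp1, osteopontin, went the other way with 1626 ± 1503 and 362 ± 260. The macrophage score was 5.30 in Yoda1 mouse 3 against 6.70 and 6.67 in the other Yoda1 mice. The list was not called without CST mouse 3 (median -0.28, adjusted p = 0.0907) or Yoda1 mouse 2 (-0.21, 0.132), and its median was -0.29 without Yoda1 mouse 1 (adjusted p = 0.0458) and -0.86 without Yoda1 mouse 3. Erythroid genes were higher in CST in 6 of 6 members (median 1.21, camera adjusted p = 1.90e-06; adjusted p = 0.525 with an estimated correlation; 3 past the threshold adjusted over the list alone), with Hbb-bs at 1196 ± 634 and 426 ± 174, Hba-a1 at 373 ± 244 and 138 ± 51.8, Hba-a2 at 69.0 ± 45.5 and 24.6 ± 12.8, and Alas2 at 5.65 ± 3.10 and 2.50 ± 0.852. Their median was 0.74 without CST mouse 2 (adjusted p = 0.000211), and they were not called with the muscle score as a covariate (0.69, adjusted p = 0.0734).

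Fibroblast and fibrillar collagen matrix genes were lower in CST in 22 of 23 members (camera adjusted p = 1.87e-08; adjusted p = 0.655 with an estimated correlation), and 0 passed adjusted over the list alone. Periostin, a matricellular protein of healing tissue encoded by Postn, measured 265 ± 94.0 in CST and 509 ± 173 in Yoda1 skin, Col6a3 39.9 ± 12.6 and 73.8 ± 29.2, Col5a2 82.7 ± 15.7 and 148 ± 61.7, and Lum 108 ± 29.0 and 177 ± 51.9. Their median was -0.43 without CST mouse 1, -0.36 without Yoda1 mouse 1, -0.35 without Yoda1 mouse 2 and -1.11 without Yoda1 mouse 3, with the list called each time. With the neutrophil score as a covariate the list was not called (-0.08, adjusted p = 0.0627). Adipocyte genes had a median of -0.51, with 14 of 16 negative (camera adjusted p = 0.000826; adjusted p = 0.753 with an estimated correlation). Yoda1 mouse 1 stood apart in them, with Fabp4, a fatty acid carrier, at 871 FPKM and the fatty acid transporter gene Cd36 at 237 against 245 and 288, and 51.0 and 73.5, in Yoda1 mice 2 and 3. Without that mouse the adipocyte median was 0.04 (adjusted p = 0.700), and the list was not called without CST mouse 2 either (-0.50, adjusted p = 0.0570). Its median was -0.77 without Yoda1 mouse 2 and -0.78 without Yoda1 mouse 3, and with the muscle score as a covariate the list was called higher in CST (0.63, adjusted p = 0.000856). That score was higher in each CST library than in each Yoda1 library, so the covariate partly stands for treatment. Myofibroblast and TGF-beta response genes (median -0.21, 14 of 18 negative, camera adjusted p = 0.0458; adjusted p = 0.753 with an estimated correlation) were not called without CST mouse 3 (median -0.11, adjusted p = 0.736), Yoda1 mouse 1 (-0.08, 0.401) or Yoda1 mouse 2 (-0.21, 0.125), and had a median of -0.33 without CST mouse 2 and -0.40 without Yoda1 mouse 3. Growth factor and angiogenesis genes (median -0.14, 14 of 19 negative, camera adjusted p = 0.0458; adjusted p = 0.753 with an estimated correlation) were not called without CST mouse 3 (median -0.02, adjusted p = 0.803), Yoda1 mouse 1 (-0.15, 0.179) or Yoda1 mouse 3, where the median was larger in size (-0.24, 0.267), and had a median of -0.29 without CST mouse 1 or Yoda1 mouse 2 and -0.34 without CST mouse 2. These 2 lists were called in 15 and 12 of 23 alternatives other than the estimated correlation.

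Among epithelial lists, hair follicle shaft and sheath genes were higher in CST in 18 of 18 members (median 1.71, camera adjusted p = 8.81e-16; adjusted p = 0.525 with an estimated correlation), with 1 member, Krtap3-1, past the threshold adjusted over the list alone. The score was 0.680, 3.00 and 4.43 in the CST libraries and averaged 0.933 ± 0.559 in the Yoda1 libraries, so CST mouse 1 lay within the Yoda1 values of 0.313 in mouse 3 and 1.09 in mouse 1. Krtap8-1 measured 3.72 ± 2.82 and 0.286 ± 0.170, Krt83 1.82 ± 1.28 and 0.204 ± 0.159, and Hoxc13, a regulator of hair keratins, 7.16 ± 6.72 and 1.59 ± 0.384. The median was 0.79 without CST mouse 3 and 2.55 without CST mouse 1, with the list called both times. Differentiating keratinocyte and cornified envelope genes were higher in CST in 27 of 28 members (median 0.45, camera adjusted p = 4.80e-07; adjusted p = 0.655 with an estimated correlation). Flg2, a filaggrin family protein, measured 19.5 ± 2.51 in CST and 10.5 ± 2.78 in Yoda1 skin, Casp14 87.4 ± 62.9 and 34.2 ± 20.8, Hrnr 31.2 ± 9.84 and 19.4 ± 7.07, and Sbsn 631 ± 233 and 410 ± 82.8. That list was not called without CST mouse 3 (median 0.10, adjusted p = 0.152), and its median was 0.69 without CST mouse 1.

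Basal keratinocyte genes (median 0.22, 14 of 15 positive, camera adjusted p = 0.0420; adjusted p = 0.753 with an estimated correlation) were not called without CST mouse 1 (median 0.08, adjusted p = 0.607), CST mouse 2 (median 0.13), Yoda1 mouse 1 (0.14, 0.520) or Yoda1 mouse 2 (0.02, 0.880), and the median was 0.39 without CST mouse 3 and 0.52 without Yoda1 mouse 3. Wound-edge and hyperproliferative keratinocyte genes (0.18, 17 of 24 positive, camera adjusted p = 0.0380; adjusted p = 0.756 with an estimated correlation) were not called without CST mouse 1, where camera's direction turned (median 0.05, adjusted p = 0.685), Yoda1 mouse 1, where the median was larger (0.31, 0.0613), or Yoda1 mouse 2 (-0.05, 0.424), and had a median of 0.40 without CST mouse 2 and 0.70 without Yoda1 mouse 3. Barrier lipid and cholesterol synthesis genes (0.21, 18 of 23 positive, camera adjusted p = 0.0383; adjusted p = 0.753 with an estimated correlation) were not called without CST mouse 3 (median 0.03, adjusted p = 0.789), Yoda1 mouse 1 (0.17, 0.276) or Yoda1 mouse 2 (0.02, 0.747). These 3 lists were called higher in CST in 14, 16 and 16 of 23 alternatives other than the estimated correlation, and with the neutrophil score as a covariate the wound-edge list was called lower (-0.36, adjusted p = 0.00419). S100a8, S100a9 and Mmp9 stand both in the wound-edge list and in that score, so the list was partly adjusted for itself.

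The other lists were not called. Melanocyte genes had a median log2 change of 0.62 (camera adjusted p = 0.0662), sebaceous gland 0.15 (0.164), Schwann and neural 0.07 (0.825), ribosomal proteins 0.03 (0.970), cell cycle -0.04 (0.156), endothelial -0.13 (0.0726), T and NK cell -0.16 (0.0948) and matrix proteases and inhibitors -0.28 (0.0869). Single libraries mattered for several of them. Melanocyte genes were called higher without CST mouse 2 (1.09, adjusted p = 0.00578) or Yoda1 mouse 1 (0.55, 0.0448), but their median was 0.06 without CST mouse 3 (0.884). With mouse number as a block (0.62, camera adjusted p = 0.0345) or no filter on low values (0.26, 0.0196) they were called higher too. Called higher were also Schwann and neural genes without Yoda1 mouse 2 (0.23, 0.0155). Called lower were endothelial genes without CST mouse 2 (-0.38, 0.000333) or Yoda1 mouse 3 (-0.42, 0.00477), T and NK cell genes without Yoda1 mouse 3 (-0.41, 0.00129), and matrix proteases without CST mouse 1 (-0.16, 0.0194) or Yoda1 mouse 3 (-0.52, 0.00653). Cell cycle genes were called higher without CST mouse 1 (0.18, 0.0216) and lower without CST mouse 3 (-0.17, 6.25e-05) or Yoda1 mouse 1 (-0.04, 0.0220). Median and mean differed in sign for pericyte and smooth muscle genes (-0.15 and 0.19, adjusted p = 0.938) and mast cell genes (-0.02 and 0.22, adjusted p = 0.487), the latter called higher without Yoda1 mouse 1 (0.27, 0.00175). In dendritic and Langerhans cell genes the median (-0.14) and mean (-0.07) were negative while camera's direction was up (adjusted p = 0.967), and without Yoda1 mouse 3 they were called lower (-0.81, 0.000323). Of the B and plasma cell list 3 of 17 genes were tested, and it was not tested as a list.

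Among annotation terms, camera called 147 of 3444 with the preset correlation (97 of GO, 38 of Reactome and 12 of KEGG), 72 higher and 75 lower in CST, and 0 with an estimated correlation. The terms with the smallest p were the Z disc (median log2 change 0.33, camera adjusted p = 5.05e-16), the I band (1.91, 6.91e-16) and the cellular response to interferon-beta (-0.59, 6.91e-16). Keratinization was higher in CST (0.44, 5.32e-12), as was glycogen metabolism (0.46, 6.38e-06). Response to virus (-0.28, 6.97e-10) and collagen formation (-0.45, 1.80e-05) were lower. Without Yoda1 mouse 3 the count of called terms was 226.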

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

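Chosen after seeing the data were limma-voom on recovered reads, leaving out CST replicate 1 with Yoda1 replicate 3, the muscle, macrophage and neutrophil scores as covariates, and each alternative for the annotation terms. The planned edgeR and DESeq2 tests on whole reads were not run, because the deposited unit is FPKM. The count of genes called by limma, 0 with 584 at an unadjusted p under 0.05, was 1348 with library weights, and 0 to 136 with single libraries left out (136 without Yoda1 replicate 2, 8 without CST replicate 2); it was 0 in the other alternatives, limma-voom included (599 unadjusted). With an estimated inter-gene correlation 0 lists and 0 annotation terms were called, against 21 and 147. The terms numbered 95 with no filter on low values, 247 with library weights, 115 to 226 with single libraries left out and 291 without CST replicate 1 and Yoda1 replicate 3. With quantile normalization 80 of 141 called terms were higher in CST, against 72 of 147. With mouse number as a replicate block limma called 0 genes (680 unadjusted), 22 lists and 145 terms; correlations of same-numbered mice were -0.08, 0.21 and -0.20, so the numbers were not taken to pair them.

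Of the 42 lists 19 had a median of one sign throughout and 23 a median that changed sign in at least 1 alternative; in 9 lists the direction turned where the list was called in either fit, as follows. With library weights the median log2 change was -0.67 for dendritic and Langerhans cells and 0.13 for cell cycle. With the muscle score as a covariate it was -0.16 for nuclear-encoded oxidative phosphorylation subunits, 0.0723 for growth factors, 0.63 for adipocytes, -0.41 for Schwann and neural and -0.20 for ribosomal proteins, which were called higher with the neutrophil score (0.44, adjusted p = 0.000952) and with library weights (0.11, 0.0350). With the macrophage score it was 0.13 for wound-edge keratinocytes, where camera's direction turned. With the neutrophil score it was -0.11 for basal keratinocytes, 0.32 for cell cycle and -0.36 for wound-edge keratinocytes, whose list shares S100a8, S100a9 and Mmp9 with that score. With single libraries left out it ran from -0.0457 to 0.70 for wound-edge keratinocytes, -0.78 to 0.0392 for adipocytes, -0.81 to 0.26 for dendritic and Langerhans cells and -0.17 to 0.18 for cell cycle. Without CST replicate 1 and Yoda1 replicate 3 it was -0.88 for dendritic and Langerhans cells and 0.20 for cell cycle. The cause was not tested. The muscle and neutrophil scores were each higher in every CST library than in every Yoda1 library. For neutrophils the margin was narrow, with 5.576 in CST replicate 3 against 5.574 in Yoda1 replicate 1. These covariates therefore partly stand for treatment, and the fits with them cannot separate the scores from it. Of the 78 tested genes named in the text 65 kept 1 sign throughout; 13 changed sign in at least 1 alternative without being called in either fit, among them Piezo1, Sting1, Cgas, Tbk1, Irf3, Glo1, Cd36 and Fabp4. Of the 78 genes 53 passed the adjusted threshold in at least 1 alternative. Most of these, such as Ccl4, Il1b and Ifit1, passed only with library weights. There Yoda1 replicate 1 had a weight of 12.8 and the other libraries 0.193 to 2.47, so that count rests largely on 1 fit. At the recovered depth 1 read on a gene of 1 kb was worth 0.0338 to 0.042 FPKM, so genes near 0 rest on few reads.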

Other observations

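The tests of causes below and the count of genes over other splits of the libraries were chosen after the results were seen; the counts of lists and terms over other splits were planned. Transcripts of embryonic and forming muscle, which is the muscle that regenerates after injury, were high in 1 library of each group; the 4 named here were chosen after their values were seen. Myl4, a myosin light chain of embryonic muscle, stood at 209 FPKM in CST mouse 2 and 246 in Yoda1 mouse 2, against 7.26 to 38.9 in the other 4 libraries. Myog, a transcription factor of muscle differentiation, stood at 55.4 and 48.8 in those 2 libraries and at 2.44 to 7.66 in the other 4. Mymk, which drives the fusion of myoblasts, stood at 56.6 and 66.0 there and at 0.896 to 6.32 in the other 4. Actc1, the cardiac actin that forming skeletal muscle expresses, stood at 633 and 528 there and at 3.61 to 63.5 in the other 4.

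Muscle transcripts higher in CST (median log2 change 3.41) were set against 2 explanations. Ongoing regeneration in CST skin would raise embryonic muscle transcripts there, and the 12 tested had a median log2 change of -0.84, with 10 negative. That median was 0.34 without Yoda1 mouse 2, -0.07 without CST mouse 3, -0.04 without CST mouse 1 and -2.20 without CST mouse 2, so its sign rests on single libraries. Without each library in turn it was at most 0.34, while the muscle list's median ran from 2.33 to 4.80. The rule set for this test asked for a negative median without each library in turn, so by that rule it could not tell. The gap to the muscle list argues only against ongoing regeneration as the whole cause, and a part for it stays open. The muscle score ranged over 4.36 within the Yoda1 group, against a difference of 3.42 between the group means. That range rests on Yoda1 mouse 2, at 6.98 against 2.62 and 4.11 in Yoda1 mice 1 and 3. The CST scores ran from 7.36 to 8.32. How much muscle each sample held may be the source, but the support for this rests on 1 library. An effect of treatment on muscle stays open, untested.

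Interferon response transcripts lower in CST (median log2 change -0.83) were set against dilution by muscle RNA and against fewer macrophages. Dilution would lower all other genes alike, but the 14534 tested genes outside both lists had a median of -0.0149 (SD 0.41). The muscle list took a mean of 2.34% of the FPKM sum in CST and 0.454% in Yoda1 skin, so its transcripts could dilute others only slightly. With the macrophage score as a covariate the list's median was -0.83 (adjusted p = 1.75e-28), where the list's adjusted p ran from 7.78e-48 to 7.48e-09 over 23 alternatives and was 0.525 with an estimated correlation. The genes outside both lists argue against dilution as the whole cause. Macrophage scores were 6.13, 5.97 and 5.54 in CST mice 1 to 3 and 6.70, 6.67 and 5.30 in Yoda1 mice 1 to 3. Only Yoda1 mouse 3 kept that score from separating the groups, so the macrophage fit rests largely on 1 library. Fewer macrophages as a cause therefore stay open. A difference between the treatments stays open, untested against an untreated group, and so does any unrecorded difference between the mice.

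Cytokine and chemokine transcripts higher in CST (median log2 change 0.51) were set against CST mouse 1 alone and against more neutrophils. Without that mouse the median was 0.41 (adjusted p = 0.00806), which argues against it as the whole cause. With the neutrophil score as a covariate the median was 0.22 (adjusted p = 0.341, range 6.84e-11 to 0.341 over 23 alternatives), while the median SE was 0.42 before and 0.43 after and the SD over members 1.39 and 0.89. The median shrank, but other lists lost their call in that fit without shrinking much. The immediate early median was 0.30 before and 0.29 after, and the senescence median 0.13 and 0.19. The lost call therefore cannot be laid to the smaller change alone. Each CST library also had a higher neutrophil score than each Yoda1 library, by 5.576 against 5.574 at the closest. The covariate therefore partly stands for treatment. A difference in neutrophil number may account for part of the change, and what recruited neutrophils was not tested.

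The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For genes past the adjusted threshold by limma, 10 of the 10 splits reached the real value of 0 (0 and 599 by limma-voom), as any split must, so that count says nothing. At an unadjusted p under 0.05 the real split had 584 genes, and 4 others had 832, 1527, 1872 and 2132. The size of the median was 0.51 for cytokines in the real split, and 0.56 and 0.63 in the splits that put CST mouse 1 with Yoda1 mouse 3 and either CST mouse 2 or CST mouse 3. For muscle it was 3.41 against a highest other of 3.28, and for the interferon response 0.83 against 0.59. For lists, 1 split, the real one, reached 21, and the highest other was 19. For annotation terms, 6 splits reached 147, and the highest other was 606, with CST mice 1 and 2 and Yoda1 mouse 1 on one side. Several times the real count may point to a structure of the samples apart from treatment or to the preset correlation, since 0 terms were called with an estimated one; this was not tested.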
